A study of Mus musculus with 8 samples.

How the data were processed

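RNA levels were measured by RNA sequencing of total RNA in mouse pancreatic ductal adenocarcinoma (PDAC) cells of the iKPC model, a genetically engineered mouse model with a doxycycline-inducible transgene and a pancreas-directed Cre recombinase. Per the labels, 4 cell lines, numbered 1 to 4, were the biological replicates, and each line was sequenced with overexpression of WT-USP21 and of ED-USP21, which gave 8 libraries. USP21 is a deubiquitinating enzyme. The labels do not spell out what ED stands for. Lines 1 and 2 carry the background label FVB/C57Bl6 and lines 3 and 4 carry C57BL/6. No library of cells without a construct was used here, and the doxycycline state of the cultures is not given in the sources used here.

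The deposited values are whole-number counts of reads per gene, not normalised, with 39179 genes and 3 rows that name no gene in each library. Per the submitters' processing notes, CASAVA, STAR, TopHat, Cufflinks and HTSeq were used with the mouse build mm9; versions and the role of each tool are not given there. The form of the deposited files, with 1 row each for reads in no gene, reads of low quality and unaligned reads, is that of HTSeq output. The row for reads in no gene held 11.4% to 20.6% of the counts, and the other 2 such rows were 0 in each library. These rows stayed out of library sizes and tests. Gene symbols are those the deposited files pair with the Ensembl identifiers, and 37607 of the 39179 identifiers are in the gene name table of the mouse annotation used here. That annotation is of a later build than mm9, so no coordinates are printed. The strand setting of the counting is not given in the sources used here, so reads of overlapping and antisense genes cannot be separated. Reads of near-identical copies, such as histone and ribosomal protein genes, are uncertain because such reads align to several places. Reads from the introduced construct and from the endogenous gene both count towards Usp21 wherever they align to it.

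From the counts, log2 fold changes and p-values were computed with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, its default filter on low counts) in R 4.3.3. Each standard error (SE) was derived from these, as the absolute log2 fold change over the square root of the F statistic of the test. Differences are WT-USP21 minus ED-USP21, so a positive log2 value means higher in WT-USP21 libraries. The p-values were adjusted by the Benjamini-Hochberg method over the 16192 genes tested, and genes with an adjusted p under 0.05 were called. The first comparison took the 4 WT-USP21 libraries against the 4 ED-USP21 libraries without the cell line. The next one took the same libraries with the cell line as a block. A further one tested whether the construct difference depended on the background label (interaction, lines as a block), and the last compared the background labels with the counts of the 2 libraries of a line summed, so that 2 lines stood against 2. Levels are given in CPM, gene counts scaled by the TMM-adjusted library totals, as mean ± SD over the 4 libraries of a group, and log2 CPM used a prior count of 2. Differences within 1 line are single differences of log2 CPM.

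The line numbers pair the libraries because both libraries of a number come from the same cell line. In a check of this pairing, the deviations of the 2 libraries of a line from their group means correlated across genes at 0.770 in line 1, 0.503 in line 2, 0.468 in line 3 and 0.347 in line 4. Libraries of lines 2 and 4 correlated across lines as well, at 0.443 for the WT-USP21 pair, 0.474 for the ED-USP21 pair, and 0.430 and 0.364 across constructs, so the check does not single out the pairing of line 4, which comes from the labels. Across constructs, libraries of line 3 correlated with those of lines 2 and 4 at 0.242 to 0.347. The values of lines 2 and 3 are thus to be read against a baseline above 0. Genes are not independent replicates, so these correlations carry no p-value.

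Before the data were examined, 32 gene lists were fixed. Each was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the 32 lists, and again with the correlation estimated from the data. Calls of members are counted over all genes tested and also adjusted over the list alone. The level of Usp21 was compared with an exact 2-sided permutation test over the 70 arrangements of the 8 libraries.

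The rule for naming genes was also fixed before the data were examined. It named 14 genes in advance, most of them of the Wnt pathway. Some genes that the rule takes are not reported here. It added up to 12 called genes per direction that differed the same way in 4 of 4 lines, with a mean of at least 1 CPM. Where fewer than 5 were found in a direction, those with the smallest p in the blocked comparison were added and are said not to pass. From each gene list described, up to 4 members with the smallest p in the blocked comparison were taken. Any gene named outside this rule is said to have been chosen after its values were seen.

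Library totals ran from 72828184 to 107551210 gene counts, with 20633 to 21510 genes detected. Intervals on counts are exact binomial 95% intervals and cover counting error only. The pipeline was tested on simulated counts drawn from the means and library sizes of these libraries, with 100 genes changed 2-fold and 100 changed 4-fold. Without the block, over 15918 genes, 35% of the 2-fold and 78% of the 4-fold changes were called, with 0 false calls. With the block, 81% and 99% were called, with 16 false calls. DESeq2 1.42.0 with the block called 89% and 100%, with 79 false calls. In these runs each changed gene had a mean of at least 1 CPM and the same change in each line. Their recovery thus need not hold for lower genes or for differences that vary between lines. The interaction, over 15885 genes, recovered 34% and 84% with 9 false calls. The comparison of background labels, over 16187 genes, recovered 79% and 99% with 12 false calls. In that run all lines were drawn from the same mean per gene. It thus held no differences between lines, unlike the real data, and its recovery does not apply to them. Of 5 gene lists raised in the simulation, 5 were called without the block at the preset correlation, 5 without the block at the estimated correlation and 5 with the block at the preset one. With the block and the estimated correlation 0 of the 5 were called, so that setting missed lists raised in this way at this sample size. Simulated genes varied independently, so the run cannot show false calls among correlated genes at the preset correlation.

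The alternatives were DESeq2 size factors, no filter on low genes, a minimum mean of 5 CPM, the DESeq2 Wald test, limma-trend, a minimum absolute log2 fold change of 1, the block added or removed, and each library or line left out in turn. After the data were seen, leaving out both libraries of line 1 was added in the unblocked gene comparison, in DESeq2 with the block and in the list tests with the block, together with read ratios with a line left out, a robust estimate of the spread and a list test of the interaction.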

Results

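The data set held 8 RNA sequencing libraries from 4 lines of mouse PDAC cells, each with WT-USP21 and with ED-USP21 overexpression. Gene counts per library were 93380985 (WT-USP21) and 107551210 (ED-USP21) in line 1, 98073396 and 72828184 in line 2, 95701546 and 95736217 in line 3, and 83762799 and 76904860 in line 4. Genes with few reads in a group are given below with a counting interval.

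Usp21 was higher with ED-USP21 than with WT-USP21 in 4 of 4 lines. With WT-USP21 its level was 147, 944, 539 and 941 CPM in lines 1 to 4, and with ED-USP21 it was 1658, 3133, 1662 and 2721 CPM. ED-USP21 libraries thus exceeded their WT-USP21 partners 11.3-fold in line 1, 3.32-fold in line 2, 3.08-fold in line 3 and 2.89-fold in line 4. The mean log2 difference, WT-USP21 minus ED-USP21, was -2.10 (SD of the 4 line differences 0.94, n = 4), with p = 0.0286 in the exact 2-sided permutation test, the smallest p it can give. Within lines, the exact sign-flip test over 16 patterns gave p = 0.125, also its smallest, and in the edgeR test over all genes Usp21 did not pass (adjusted p = 0.205 with the block and 0.9999 without it). Endogenous and introduced Usp21 reads were not separated, and no library without a construct was used here, so neither level is a fold over the parental cells. Every difference between the constructs below therefore goes with a difference in Usp21 amount as well as in its form.

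The comparison of WT-USP21 with ED-USP21 asks which transcripts differ with the construct, that is, with the form and the amount of Usp21 together. Within cell lines, 4 genes rose with WT-USP21 relative to ED-USP21 and 0 fell. Stra6 (ENSMUSG00000032327), a membrane receptor for retinol-binding protein, stood at 32.9 ± 13.4 CPM against 5.41 ± 1.93 CPM (SD, n = 4 each), a log2 difference of 2.54 (SE 0.18). Prickle1 (ENSMUSG00000036158), a planar cell polarity protein of non-canonical Wnt signalling, stood at 11.02 ± 4.04 against 3.31 ± 1.11 CPM (log2 1.71, SE 0.13). Dclk1 (ENSMUSG00000027797), a kinase used as a marker of tuft cells and of stem-like pancreatic cells, stood at 53.4 ± 37.1 against 17.2 ± 12.1 CPM (log2 1.63, SE 0.10). Each of the 4 called genes was higher with WT-USP21 in 4 of 4 lines, with an edgeR adjusted p of 0.0416.

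Without the block edgeR called 0 of 16192 genes, with 392 at an unadjusted p under 0.05, fewer than chance alone gives on average. In that comparison DESeq2 called 60 genes (50 higher, 10 lower with WT-USP21) and limma-trend called 3. With the block, edgeR found 1341 genes at an unadjusted p under 0.05, and DESeq2 called 406 genes (315 higher, 91 lower). The count was 0 without line 2, 0 without line 3 and 0 without line 4, while the log2 differences moved little with a line left out (1.52 to 1.71 for Dclk1, 2.41 to 2.71 for Stra6 and 1.61 to 1.77 for Prickle1). It was also 0 with a minimum mean of 5 CPM and 1 with a robust estimate of the spread. It was 746 (409 higher, 337 lower) without line 1, and those 746 included the 4. With both libraries of line 1 left out of the unblocked comparison, a choice made after the data were seen, edgeR called 383 genes.

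**Figure D1:**
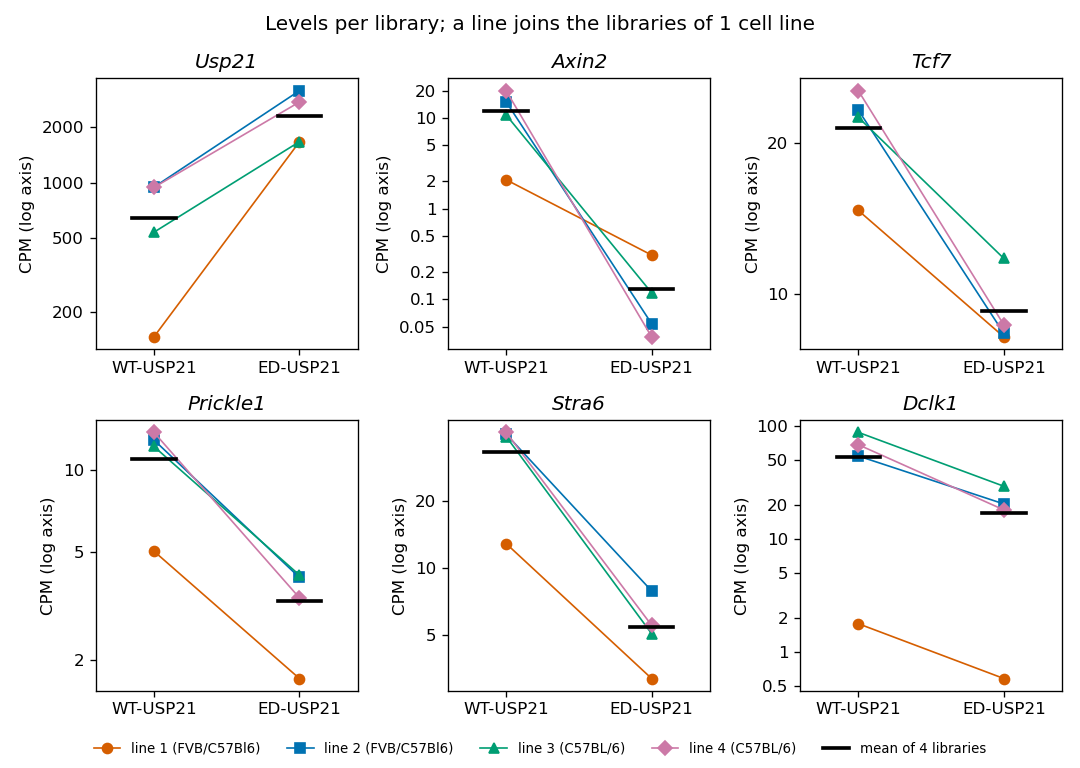
Level of 6 genes in CPM (vertical, log axis) in the WT-USP21 and ED-USP21 libraries (horizontal); each coloured line joins the libraries of 1 cell line and the black bar is the mean of 4 libraries. Usp21 is higher with ED-USP21 in 4 of 4 lines, while Axin2, Tcf7, Prickle1, Stra6 and Dclk1 are higher with WT-USP21 in 4 of 4 lines, although Usp21, Axin2 and Tcf7 did not pass the blocked edgeR test over all genes.

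Genes that came next in the blocked comparison did not pass. Kalrn had a log2 difference of 0.96 (SE 0.08, edgeR adjusted p = 0.0632) and was higher with WT-USP21 in 4 of 4 lines. In the other direction the genes with the smallest p were Smpdl3b (log2 -0.88, adjusted p = 0.102), Frat2, a binding partner of GSK-3 in Wnt signalling (-0.55, 0.144), Plat, the tissue plasminogen activator (-0.38, 0.160), Fam65b (-0.43, 0.162) and Pgm2 (-0.37, 0.184). Each of these 5 was lower with WT-USP21 in 4 of 4 lines.

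Targets of Wnt/beta-catenin signalling lay towards WT-USP21, with the smallest camera p of the 32 lists. The 14 tested members had a median log2 difference of 0.69, and the list median was positive in each line, at 0.43, 0.74, 0.63 and 0.93 in lines 1 to 4. Over all genes tested edgeR called 0 members, with or without the block, whereas DESeq2 with the block called 8 higher and 0 lower. Adjusted over the list alone, 5 members in edgeR were higher and 0 lower without the block, and 8 were higher and 0 lower with it. The camera test called the list higher with WT-USP21 (adjusted p = 1.28e-14, and 3.66e-10 with the block), but adjusted p = 0.0826 with an estimated correlation and adjusted p = 0.372 with that and the block.

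Axin2 (ENSMUSG00000000142), the feedback inhibitor read as a general Wnt target, stood at 12.01 ± 7.61 CPM with WT-USP21 and at 0.130 ± 0.124 CPM with ED-USP21 (SD, n = 4 each). Its WT-USP21 libraries held 4468 reads in all and its ED-USP21 libraries 50, a ratio, scaled to the library totals, of 85.0 (95% interval 64.4 to 114.8). Without line 1, which held 32 of the 50 reads, the ratio was 210.1, and without line 4 it was 56.2. Its log2 difference within lines was 2.67 in line 1, 7.63 in line 2, 6.27 in line 3 and 8.37 in line 4, and with this spread the edgeR adjusted p was 0.197 with the block. Lgr5, the Wnt-dependent receptor that marks intestinal stem cells, had 685 reads with WT-USP21 and 5 with ED-USP21, a ratio of 130.4 (95% interval 55.6 to 402.9), and an edgeR adjusted p of 0.0705 with the block. Its reads were 60 against 1 in line 1, 234 against 4 in line 2, 172 against 0 in line 3 and 219 against 0 in line 4. Without line 2 the ratio was 463.1 (95% interval 82.7 to 18330), from 451 reads against 1. It was lowest without line 4, at 89.6 (95% interval 38.1 to 277.3). Lef1, a transcription factor of the TCF family, was too low to test, with 38 reads in WT-USP21 and 3 in ED-USP21 libraries. Its ratio was 12.1 (95% interval 3.83 to 61.1). With a line left out it was highest without line 2, at 24.6 (95% interval 4.02 to 1014), and lowest without line 4, at 9.94 (3.10 to 50.8). These intervals cover counting error only, and the ratios with a line left out were added after the data were seen.

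The other members of the list that are named here moved less. The receptor Ephb2 stood at 7.55 ± 4.65 against 1.33 ± 1.06 CPM (log2 2.51, SE 0.25, edgeR adjusted p = 0.0692) and the receptor Ephb3 at 14.5 ± 7.62 against 8.95 ± 4.74 CPM (log2 0.70, SE 0.09, adjusted p = 0.0987). Tcf7 (ENSMUSG00000000782), another TCF family transcription factor, stood at 21.4 ± 4.69 against 9.24 ± 1.69 CPM (log2 1.20, SE 0.15, adjusted p = 0.104). Each was higher with WT-USP21 in 4 of 4 lines. Cd44 had a log2 difference of 0.41 (SE 0.08, adjusted p = 0.273). The Wnt targets Myc (log2 0.00, SE 0.09), Ccnd1 (0.15, SE 0.09) and Sox9 (-0.15, SE 0.14) did not pass in the blocked comparison, nor did the beta-catenin gene Ctnnb1 (0.01, SE 0.10) or its partner Tcf7l2 (-0.07, SE 0.18). Yap1 (-0.01, SE 0.06) and the kinase gene Mark3 (0.11, SE 0.06) did not pass either. Without line 1, 8 of the 14 Wnt targets rose over all genes tested and 12 did so adjusted over the list alone.

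The 8 other lists in this direction lay towards WT-USP21 at the preset correlation, and each lost its call with an estimated one. Wnt ligands and receptors (23 tested, median log2 0.22, adjusted p = 0.0156, adjusted p = 0.190 with an estimated correlation) held Wnt5a at 2.56 ± 0.439 against 0.812 ± 0.401 CPM (log2 1.78, SE 0.43) and Wnt7b with a log2 difference of 1.30 (SE 0.34). Of that list edgeR called 0 members over all genes, and 5 higher and 1 lower adjusted over the list alone with the block; DESeq2 with the block called 4 higher and 1 lower over all genes. Targets of YAP and TEAD (23 tested, median 0.08, adjusted p = 0.0139) and of TGF-beta (15 tested, median 0.22, adjusted p = 0.0322) had adjusted p = 0.463 each with an estimated correlation. With the block, 5 YAP targets and 4 TGF-beta targets were higher and 0 lower adjusted over the list alone. The YAP targets included Igfbp3 (log2 0.86, SE 0.17) and Rbms3 (1.58, SE 0.27), and the TGF-beta targets Pmepa1 (0.51, SE 0.09) and the integrin gene Itgb6 (0.86, SE 0.19).

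RAS-MAPK output genes (20 tested, median log2 0.10) were called without the block (adjusted p = 0.0383, adjusted p = 0.573 with an estimated correlation) but not with it (adjusted p = 0.106). Adjusted over the list alone with the block, 1 member was higher and 1 lower. Dusp4, a MAP kinase phosphatase, had a log2 difference of 0.62 (SE 0.10), and Epha4 one of -0.34 (SE 0.07). Notch pathway genes (14 tested, median 0.16) were called with the block alone (adjusted p = 0.0106, against 0.0900 without it, and adjusted p = 0.372 with the block and an estimated correlation). Their ligand gene Dll4 had a log2 difference of 0.94 (SE 0.19) and the effector Hes1 one of 0.31 (SE 0.09). Lysosome and autophagy genes (22 tested, median 0.07) had adjusted p = 0.0423, and adjusted p = 0.710 with an estimated correlation.

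Mesenchymal genes (14 tested, median log2 0.14, adjusted p = 0.0330, adjusted p = 0.573 with an estimated correlation) differed between lines, with medians of -0.20 in line 1 and 0.33, 0.24 and 0.62 in lines 2, 3 and 4. Cdh2, the N-cadherin gene, stood at 142 ± 13.7 against 97.0 ± 40.5 CPM (log2 0.63, SE 0.18), and the fibronectin gene Fn1 at 462 ± 216 against 293 ± 288 CPM (log2 0.95, SE 0.27). Fibroblast markers (6 tested, median 0.85, adjusted p = 0.0327) and endothelial markers (6 tested, median 0.63, adjusted p = 0.0421) had adjusted p = 0.463 each with an estimated correlation. Fibroblast medians were -0.04, 0.04, 0.33 and 1.64 in lines 1 to 4, so the shift lay mainly in line 4. Endothelial medians were -0.10, 0.44, 0.58 and 0.32. Over all genes, edgeR called 0 members of these 3 lists, while DESeq2 with the block called 3 mesenchymal genes, 1 fibroblast marker and 1 endothelial marker higher. Collagen gene Col5a1 stood at 130 ± 75.4 against 92.9 ± 97.9 CPM, whereas Col1a1 reached 2.89 ± 1.31 CPM. Kdr, the VEGF receptor gene, stood at 4.81 ± 3.31 against 0.327 ± 0.219 CPM (log2 3.74, SE 0.35, edgeR adjusted p = 0.0692) and was higher with WT-USP21 in 4 of 4 lines.

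The 7 lists called lay towards ED-USP21 at the preset correlation, with 0 members called by edgeR over all genes and 0 adjusted over the list alone. DESeq2 with the block called 1 integrated stress response gene and 1 histone gene lower over all genes. Hypoxia and glycolysis genes (19 tested, median log2 -0.24) had a negative median in each line, at -0.48, -0.09, -0.25 and -0.19 in lines 1 to 4 (adjusted p = 2.01e-06, adjusted p = 0.190 with an estimated correlation). Among them were Egln3 (log2 -0.40, SE 0.11), an oxygen-sensing prolyl hydroxylase, and Pdk1 (-0.30, SE 0.09), a kinase that limits pyruvate oxidation. Cell cycle genes (27 tested, adjusted p = 7.73e-06, adjusted p = 0.588 with an estimated correlation) had a median of -0.81 in line 1 but -0.02, 0.01 and -0.03 in the other lines. Replication-dependent histone genes (62 tested, adjusted p = 0.00317, adjusted p = 0.778 with an estimated correlation) had a median of -0.84 in line 1 and -0.16, 0.17 and 0.26 in lines 2, 3 and 4. Histone genes took 0.394% of the counts of the WT-USP21 library of line 1 and 0.558% to 0.831% in the other libraries.

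Basal-like PDAC genes (9 tested, median log2 -0.24, adjusted p = 0.0404) had adjusted p = 0.463 with an estimated correlation, with a median of 0.40 in line 1 and -0.44, -0.41 and -0.68 in the others. Integrated stress response genes (20 tested, median -0.13, adjusted p = 0.0480, adjusted p = 0.778 with an estimated correlation) had a median of 0.23 in line 1 and -0.16, -0.21 and -0.30 in lines 2, 3 and 4. They included the serine synthesis enzyme gene Psat1 at 610 ± 47.3 against 718 ± 47.8 CPM (log2 -0.24, SE 0.06). Cytosolic ribosomal protein genes (83 tested, median -0.06) had adjusted p = 0.00142, and adjusted p = 0.710 with an estimated correlation. Their median was 0.11 in line 2, the other direction, and -0.17, -0.15 and -0.04 in lines 1, 3 and 4. Immune cell markers (4 tested, median -0.34, adjusted p = 0.0423, adjusted p = 0.573 with an estimated correlation) were near the floor for the pan-leukocyte gene Ptprc, at 0.0886 ± 0.0346 against 0.188 ± 0.0891 CPM.

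Stem and progenitor markers (16 tested, median log2 0.01) were not called by camera (adjusted p = 0.808), although Dclk1 in this list rose. Epithelial genes (18 tested, median -0.17, adjusted p = 0.164) and classical PDAC genes (18 tested, median -0.09, adjusted p = 0.798) were not called either. In both, line 1 went the other way from the rest, with epithelial medians of 0.47 in line 1 and -0.43, -0.24 and -0.60 in lines 2, 3 and 4. Krt19, a ductal keratin gene, stood at 1454 ± 761 against 1696 ± 198 CPM (log2 -0.34, SE 0.20).

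**Figure D2:**
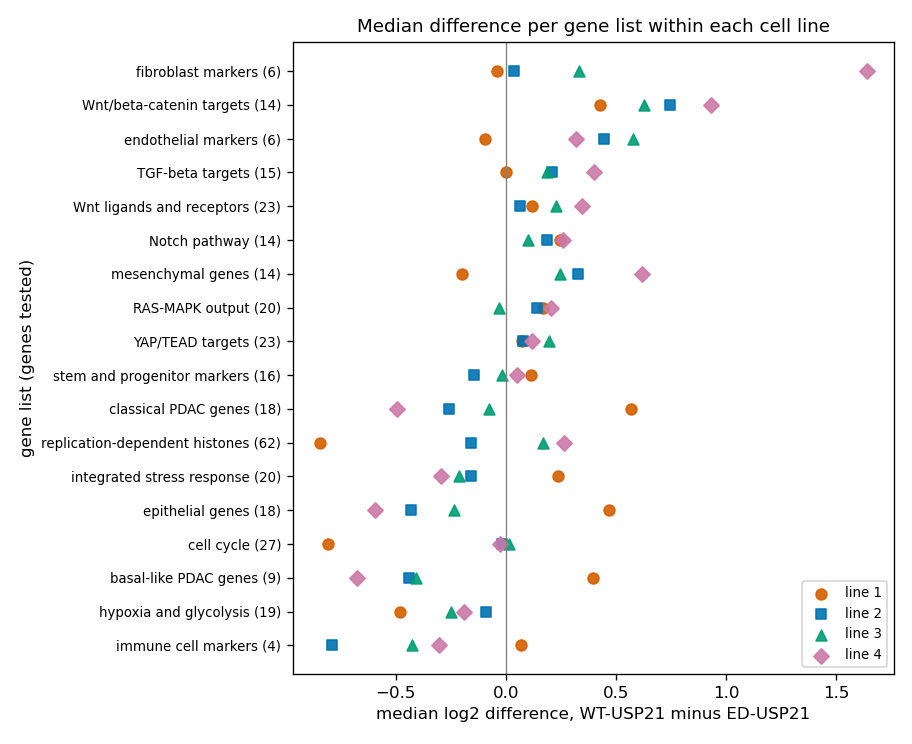
Median log2 difference, WT-USP21 minus ED-USP21 (horizontal), of the tested genes of 18 lists (vertical, number of genes tested in brackets) in each of the 4 cell lines (points). The Wnt/beta-catenin targets lie above 0 in each line, from 0.43 to 0.93, while the cell cycle genes lie at -0.81 in line 1 and near 0 in the other lines.

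Line 1 differed from the other lines more than the constructs differed within any line, whereas lines 2 and 4 lay closer together than the constructs within them. The first principal component of log2 CPM held 63.8% of the variance and parted line 1 from lines 2, 3 and 4. Between the WT-USP21 libraries of lines 1 and 2, 3833 genes were at least 2-fold apart, against 717 between those of lines 2 and 4 and 703 between their ED-USP21 libraries. WT-USP21 and ED-USP21 libraries of 1 line were apart by 1515 genes in line 1, 1333 in line 2, 1167 in line 3 and 1718 in line 4. The library nearest to each library of line 2 was that of line 4 with the same construct. The median chi-square per gene was 3.54 for the WT-USP21 and 2.80 for the ED-USP21 libraries of these lines, above sampling noise, so each was counted as its own library. Lines 2 and 4 are thus not shown to be independent of each other, which limits each n of 4 and each statement on 4 of 4 lines given here.

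**Figure D3:**
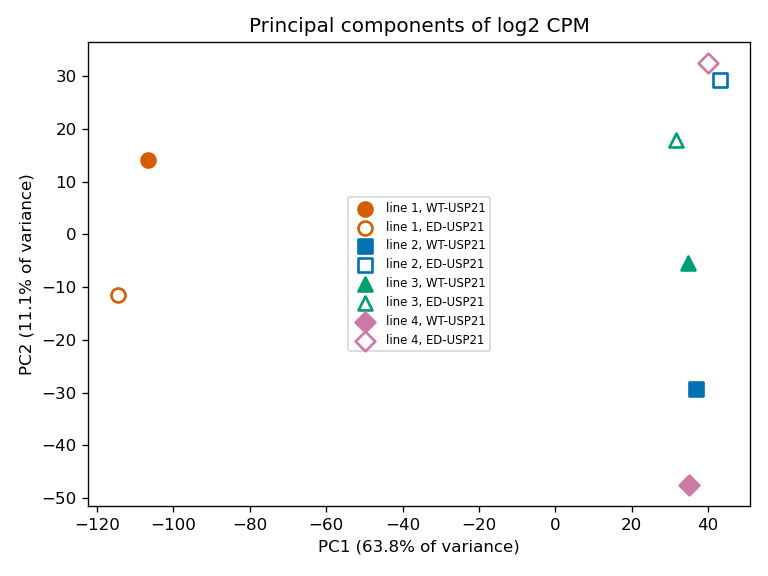
First principal component (horizontal, 63.8% of variance) against the next one (vertical, 11.1% of variance) of log2 CPM for 8 libraries; colour and shape give the line, filled symbols are WT-USP21 and open symbols ED-USP21. Line 1 lies apart from the other lines on the horizontal axis, and the ED-USP21 libraries of lines 2 and 4 lie close together.

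Few or no genes were called by background label with all lines in, which does not show that few differ. Lines 1 and 2 share a label but lay far apart, a spread that can hide a difference between labels. The difference of the construct effect between the FVB/C57Bl6 and C57BL/6 lines gave 0 genes in edgeR, with 375 of 16192 at an unadjusted p under 0.05. Comparing the lines by label, with 2 lines against 2, edgeR called 0 of 17897 genes, with 162 at an unadjusted p under 0.05. Each of these counts of unadjusted p lay below what chance alone gives on average. By label, DESeq2 called 7 genes and limma-trend 0. Without line 2, so that line 1 alone stood for the FVB/C57Bl6 label and was assumed to vary like the C57BL/6 lines, 4610 genes were called (2732 higher, 1878 lower in line 1), and without line 1 the count was 8.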

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

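Of the explanations weighed here, the tests of line 1 were all chosen after its departure had been seen, and the list test of the interaction was added after the data were seen.

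Among 56 groups of 4 libraries examined (library measures and named genes), 6 had 1 library far from the others, where chance gives about 1 in 20, or 2.8. Of these, 3 were WT-USP21 levels of called genes in line 1: Stra6 at log2 CPM 3.68 against 5.28 to 5.34 in the other lines, Prickle1 at 2.34 against 3.62 to 3.79, and Dclk1 at 0.86 against 5.77 to 6.47. The ED-USP21 library of line 1 stood apart for Dclk1 at -0.71 (others 4.19 to 4.88) and for Ccnd1 at 10.05 (others 10.63 to 10.68). The ED-USP21 library of line 3 stood apart for Tcf7 at 3.56 (others 3.04 to 3.12).

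The construct effect on 13 gene lists differed between the FVB/C57Bl6 and the C57BL/6 lines in the camera test of the interaction at the preset correlation, and on 0 with an estimated correlation, where the adjusted p ran from 0.697 to 0.949 over the lists. Cholesterol synthesis genes were relatively higher with WT-USP21 in the FVB/C57Bl6 lines (adjusted p = 7.38e-13), with medians of 0.28 and 0.20 in lines 1 and 2 against -0.10 and -0.28 in lines 3 and 4. In the same direction lay the integrated stress response (adjusted p = 4.04e-05), classical PDAC genes (0.00255), epithelial genes (0.00568), basal-like PDAC genes (0.00782) and oxidative phosphorylation (0.0423). The opposite direction held replication-dependent histones (adjusted p = 7.86e-23), the cell cycle (2.23e-06), mesenchymal genes (0.00255), Wnt/beta-catenin targets (0.00741), mitochondrially encoded genes (0.0107), fibroblast markers (0.0409) and TGF-beta targets (0.0423). For the cell cycle, epithelial, mesenchymal, basal-like, classical PDAC and integrated stress response lists line 2 lay with lines 3 and 4, so their difference by label came from line 1. For Wnt/beta-catenin and TGF-beta targets the line 2 medians (0.74 and 0.21) also lay between those of lines 3 and 4, and line 1 was lowest (0.43 and 0.00). Oxidative phosphorylation medians were -0.08, 0.13, -0.06 and -0.01 in lines 1 to 4, so line 2 alone lay above 0. Medians of mitochondrially encoded genes were -0.04, -0.31, 0.51 and 0.03, with lines 1 and 4 near 0.

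Line 1 departed from the other lines in its construct differences. An exchange of its 2 construct labels was argued against by the 8 Wnt targets called without it, whose median difference in line 1 was 0.77, with 7 of 8 above 0 and a quartile range of 0.45 over all genes. A weaker form of the same effect, acting on its own, was argued against for genes lower with WT-USP21 in lines 2, 3 and 4. Of those 333 genes that were also tested with all lines, 15.9% shared the sign in line 1 and their median there was 0.40. For the 403 genes higher in those lines, 51.4% shared it, no more than the 51.4% of all genes that were higher with WT-USP21 in line 1. Their median was 0.02 in line 1 against 0.90 in lines 2, 3 and 4. As a set they thus shared no direction beyond that of all genes, which leaves a weaker form undecided for them. A different growth state of the 2 libraries of line 1 may contribute and stays open: the cell cycle median there was -0.81, with 27 of 27 genes below 0, against -0.02, 0.01 and -0.03 in the other lines. Such a difference could mask a weaker construct effect in this 1 pair of libraries, so the 2 together are not excluded. Line 1 also had the lowest Usp21 level with WT-USP21, at 147 CPM against 539 to 944 CPM in the other lines. Whether that bears on its departure was not tested. Line 2 carries the same strain label as line 1, and its cell cycle (-0.02) and epithelial (-0.43) medians lay with those of lines 3 and 4.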

How the results depend on the processing

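Leaving out both libraries of line 1 in the unblocked gene comparison, the robust spread, DESeq2 without line 1, the blocked list tests without line 1 and the list test of the interaction were chosen after the data were seen; the other alternatives were planned. For the unblocked comparison (0 genes), DESeq2 called 60, limma-trend 3, the replicate block 4, and leaving out both libraries of line 1 383; leaving out 1 library gave 0 to 11 genes, with 11 without the WT-USP21 library of line 1. For the blocked comparison (4 genes), no filter on low genes gave 58 (55 higher, 3 lower), a minimum of 5 CPM 0, DESeq2 406, no replicate block 0, the robust spread 1, and DESeq2 without line 1 1502 (747 higher, 755 lower). Leaving out a line gave 0 to 746 genes, and the 4 genes were among those called with no filter, by DESeq2, by limma-trend and without line 1. With 79 false calls in simulation, the DESeq2 counts are the less certain. The cause of these shifts was not tested. The interaction gave 0 genes in each alternative run. The background comparison (0 genes) gave 7 with DESeq2 and 0 to 4610 with a line left out.

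The camera count of 16 lists was 16 with the replicate block (15 shared), 11 at a minimum of 5 CPM, 0 with an estimated correlation, 0 with that and the block, and 0 with that, the block and line 1 left out; with a line left out it was 5 to 13. For Usp21 the log2 difference stayed between -1.62 and -2.28 with a line left out, where the exact p of 0.1 is the smallest that 3 against 3 libraries give, and was -2.10 under the replicate block (p = 0.125, the smallest). DESeq2 size factors gave -2.09 and library size alone -2.07. Among named genes no called direction reversed; the 4 called genes lost their call without the block and without line 2, 3 or 4, and DESeq2 added calls for 30 and leaving out line 1 for 32. Depth limits Lgr5, Axin2 and Lef1 in ED-USP21 libraries, where a library held 0 to 32 reads.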

Other observations

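The genes and lists described for lines 2, 3 and 4, the tests of the distances between lines and the count of lines with higher Usp21 were chosen after the data were seen. The count of genes without line 1 in the blocked comparison, the Usp21 values under other scaling and with a line left out and the counts over other splits of the libraries were planned, but the bounds that the Usp21 values were held to were set after they were seen.

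Without line 1, the blocked comparison held 746 genes, and the genes named here were chosen after their values were seen. Axin2 rose by a log2 difference of 7.63 (SE 0.34), Kdr by 3.90 (SE 0.19), the metalloproteinase inhibitor gene Timp3 by 3.83 (SE 0.30), the chondroitin sulfotransferase gene Chst11 by 3.31 (SE 0.13) and the nebulette gene Nebl by 2.87 (SE 0.11). Genes that fell with WT-USP21 included Psca, a surface antigen of gastric and pancreatic tumours (log2 -2.56, SE 0.49), Ddc, the aromatic amino acid decarboxylase (-2.48, SE 0.31), the prostaglandin transporter gene Slco2a1 (-1.82, SE 0.24), the glutathione transferase gene Gsta1 (-1.93, SE 0.32) and the gastric trefoil factor gene Tff1 (-1.77, SE 0.26). In line 1 the last 5 differed by 0.48, 0.05, 0.18, 0.77 and 2.58, the opposite sign. The 5 raised genes kept their sign there, at 2.67, 0.66, 0.99, 0.70 and 0.05, although Nebl and Ddc, at 0.05 each, lay near 0. Other genes went otherwise: Gm10801 fell (log2 -2.70) and also fell in line 1 (-2.47), while Sirpa rose (2.92) but fell in line 1 (-1.85). Of the called genes also tested with all lines, 51.4% of 403 raised and 15.9% of 333 lowered genes kept their sign in line 1. Of all genes, 51.4% were higher there with WT-USP21.

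Gene lists moved in the same 3 lines. Of 14 mesenchymal genes 4 rose and 0 fell over all genes tested (7 and 0 adjusted over the list alone), and of 18 epithelial genes 0 rose and 5 fell (0 and 9). Classical PDAC genes split 1 higher and 4 lower of 18. Of 20 integrated stress response genes 0 rose and 4 fell (0 and 15), with a median log2 difference of -0.20. TGF-beta targets rose in 4 and fell in 0 of 15. Among markers of other cell types, 2 of 6 endothelial markers rose and 0 fell (median 0.47, camera adjusted p = 0.00196), and 0 of 4 immune cell markers rose and 1 fell (median -0.53, camera adjusted p = 0.0147). Of 6 fibroblast markers 1 rose, and the list was not called (median 1.20, camera adjusted p = 0.0634). With an estimated correlation none of these lists was called (adjusted p = 0.743 for the fibroblast markers and 0.575 for each of the others). Lines 2 and 4 lay close together, so these 3 lines are not shown to be 3 independent replicates, a limit that holds for the 4 lines too.

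Over the 35 splits of the 8 libraries into 4 and 4, the real one gave 0 genes without the block, which each of the 35 matched; the highest other gave 4. For the gene lists, 2 of 35 splits gave at least the 16 of the real one, the highest other 17, so chance cannot be excluded for that count. The split with 17 parted 2 lines, whereas the 7 others that part all 4 lines gave 4 to 10 lists. Over the 34 other splits the median was 7 lists, so splits that do not follow the constructs also had lists called at the preset correlation. With the block there are 8 splits, too few for a share under 0.05: the real one gave 4 genes and the highest other 0, and 1 of 8 reached that count.

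Usp21 was higher in ED-USP21 libraries. Scaling between libraries was argued against, as library size alone gave a log2 difference of -2.07. A single line as the source was argued against, since the difference nearest 0 with a line left out was -1.62. Whether the genes higher with WT-USP21 follow the enzyme's form or the lower amount of Usp21 cannot be told apart, because Usp21 was higher with ED-USP21 in 4 of 4 lines; a feedback on the transcript or unequal vector delivery may each produce that, and neither was tested.

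Lines 2, 3 and 4 lay close together across the background labels. A library counted under 2 names was argued against by the smallest median chi-square per gene over all pairs of libraries, 2.80. The background strain as the main source of the profile was argued against, as lines 2 and 4 were on average 710 genes apart by 2-fold and lines 1 and 2 3938.5. A shared origin of lines 2, 3 and 4 may account for it and stays open: 0 genes were on in one of them (5 CPM or more) and off in another (0.1 CPM or less), while 20, 27 and 14 genes were so between line 1 and lines 2, 3 and 4.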
